A study of Homo sapiens with 12 samples.

How the data were processed

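The series holds 12 Affymetrix arrays of total RNA from 2 human lymphoma cell lines, HuT78 and Raji, each untreated or treated with hydralazine and valproate, with 3 biological replicates in each of the 4 groups. Per the labels' protocols, cells were grown in a supplemented RPMI medium, the medium with the drugs was replaced daily, RNA was isolated with TRIzol, and biotin-labelled cRNA was prepared from 2 µg of total RNA. The series description gives 200 ng of RNA in place of this amount. The deposited values are log2 signals, 1 per transcript cluster and array, with 0 missing values. Transcriptome Analysis Console version 4.0 was used, per the submitters' processing notes. The background correction, the normalization, the summary of probes and whether a signal stood above background are not given in the sources used here. The values of the arrays within a line have nearly the same distribution and those of the lines differ, with a gap of 1.72 between the median log2 signals over all clusters and 1.82 over the named genes.

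All 12 value columns were assigned to a sample and none was left out. Of 53617 transcript clusters, 16098 had 1 gene symbol, 0 had several and 37519 had none. Symbols were checked by gene ID against a table of human genes of the assembly GRCh38.p14, in which all 16098 were found, and that table was used only for names and gene types. The genome build of the array is not given in the sources used here, so no coordinates are printed. Where a gene had several clusters (779 genes), the cluster with the highest mean over the 12 arrays stood for it, which left 14884 genes. No filter on dim signals was applied, and the number of arrays sets the precision.

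The following choices were made before the data were examined: the contrasts, the model, the threshold, the gene lists, the rule for named genes and all alternatives except the pair marked below. A mean per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with neither trend nor robust setting) over the 12 arrays, so that the 4 groups shared 1 estimate of the spread (8 residual and 3.93 prior degrees of freedom). The contrasts were treated minus untreated in each line, the difference of these effects (HuT78 minus Raji), and untreated HuT78 minus untreated Raji. All tests were two-sided, and p values were adjusted by the method of Benjamini and Hochberg over 14884 genes, with a threshold of 0.05. The effects of the lines were correlated across genes, and the overlap of the called genes was set against the count for independent lists.

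Of 40 fixed gene lists, 36 had at least 5 measured members and were tested with camera at its preset correlation of 0.01, adjusted over the lists of a contrast. The 4 lists not tested covered death receptors, MHC class II, replication-dependent histones and the proteasome. Tested lists were often measured only in part, such as 14 of 40 cancer-testis, 8 of 20 growth-arrest and 14 of 25 p53 target genes. Beside each list stands its camera p with a correlation estimated from the data, and members were also adjusted over the list alone. The named genes were the 8 largest rises and 8 largest falls per treatment contrast among genes past the threshold whose 3 arrays per group did not overlap, and 5 in each direction for the other contrasts. For each list described, up to 4 of the most changed called members could be named (the 2 with the smallest p where fewer than 2 passed), and 12 fixed genes of the drugs' targets and responses were added, of which those with a named cluster are reported. Pseudogenes, genes of small or unnamed RNAs, XIST and Y-linked genes were left out. Genes outside this rule are marked as chosen after their values were seen.

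Alternatives were quantile normalization, median centring of each array, a filter on dim genes, the mean of a gene's clusters, all transcript clusters, eBayes with trend and robust settings, a block for the replicate number, each array or replicate number left out in turn, only the 6 arrays of a comparison, 2-fold thresholds, camera with an estimated correlation, and fry. A spread estimated per line for the difference, and the 6 arrays of each line for the overlap, were added after seeing the data.

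The code was tested on simulated data with the real genes' means and spreads (14884 genes). In each line 50 genes were changed at each of 1.25-, 1.5-, 2- and 4-fold. For HuT78, 6% of genes changed 1.25-fold, 72% of those changed 1.5-fold and all of those changed 2-fold were recovered, with 7 false calls. For Raji the shares were 20%, 68% and 98%, with 37 false calls, and on the 6 Raji arrays alone 8%, 48% and 94%, with 12 false calls. For the difference they were 6.06%, 37% and 86.9%, with 16 false calls. From the smallest to the largest change, 10, 34, 49 and 50 genes were recovered in Raji beside its 37 false calls. In HuT78 these numbers were 3, 36, 50 and 50, beside 7 false calls. With the shared spread, false calls in simulated Raji data thus made up a larger share of all calls than the threshold of 0.05 allows. Both simulated lists shifted by 0.3 were recovered in each line, with 1 false list in HuT78 and 0 in Raji. The simulated genes varied independently of each other, and camera used its preset correlation. These numbers therefore do not show how many false lists the correlation between real genes would give. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the table and drew the figures.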

Results

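Total RNA of HuT78, a cell line from a cutaneous T-cell lymphoma, and of Raji, a B-cell line from a Burkitt lymphoma, was measured on 12 Affymetrix arrays. Each line gave 3 arrays of untreated cells and 3 arrays of cells treated with hydralazine and valproate, called biological replicates by the labels. Hydralazine is a vasodilator that has also been used to inhibit DNA methylation, and valproate inhibits histone deacetylases. The doses and the length of the treatment are not given in the sources used here. The log2 signals covered 53617 transcript clusters, and the 16098 clusters with a gene symbol stood for 14884 genes, 11916 of them protein-coding. Median signals over all clusters were 5.37 to 5.41 on the HuT78 arrays and 3.67 to 3.73 on the Raji arrays, so the lines sat on different scales and each effect of treatment was taken within a line. The number of arrays limits the precision. Values below are log2 fold changes of treated over untreated cells ± SE with n = 3 arrays per group. The largest changes in a line were picked only among genes with all 3 treated arrays on one side of all 3 untreated arrays. Of 14884 genes, 4393 in HuT78 and 4350 in Raji met this condition, where a random order of arrays gives 10%.

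In HuT78 the comparison asked which transcripts the drug combination changed in a T-cell lymphoma line. SUCNR1, the receptor for succinate, rose by 2.82 ± 0.12, which is 7.07-fold (adjusted p = 3.29e-07), from a log2 signal of 6.64 ± 0.12 to 9.46 ± 0.11 (SD). TLR6, a receptor for bacterial lipopeptides, rose by 2.06 ± 0.13 (adjusted p = 7.42e-06) from a dim log2 signal of 3.87, under the lower quartile of the untreated HuT78 arrays (4.02 to 4.04), and LAIR2, a secreted collagen-binding decoy receptor, rose by 1.82 ± 0.22. CXCR3, the receptor for the chemokines CXCL9 and CXCL10, changed by -1.56 ± 0.14 (adjusted p = 0.000103), and NKG7, a membrane protein of cytotoxic granules, by -1.29 ± 0.10 (adjusted p = 6.43e-05). The next largest rises were SLAMF7, a cell surface receptor of lymphocytes (1.59 ± 0.09), HIPK2, a nuclear kinase that responds to DNA damage (1.56 ± 0.18), and HMGN5, a nucleosome-binding protein (1.46 ± 0.09). TPMT, which methylates thiopurine drugs, rose by 1.45 ± 0.11 and ATRNL1 by 1.42 ± 0.12. Falls of about 2-fold were measured for NSMF (-1.18 ± 0.11), SUSD4, a complement regulator (-1.13 ± 0.11), and TLR5, the flagellin receptor (-1.08 ± 0.11). GZMK, a granule protease, changed by -1.06 ± 0.14, LGMN, a lysosomal protease, by -1.05 ± 0.11, and LAT, an adaptor of T-cell receptor signalling, by -0.98 ± 0.15. In all, 889 of 14884 genes passed an adjusted p of 0.05 in limma, 650 higher and 239 lower, and 57 of them changed at least 2-fold (50 higher, 7 lower). With 1 array left out the count was 476, 562 and 424 without untreated HuT78 array 1, 2 or 3, and 495, 471 and 534 without treated array 1, 2 or 3.

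**Figure D1:**
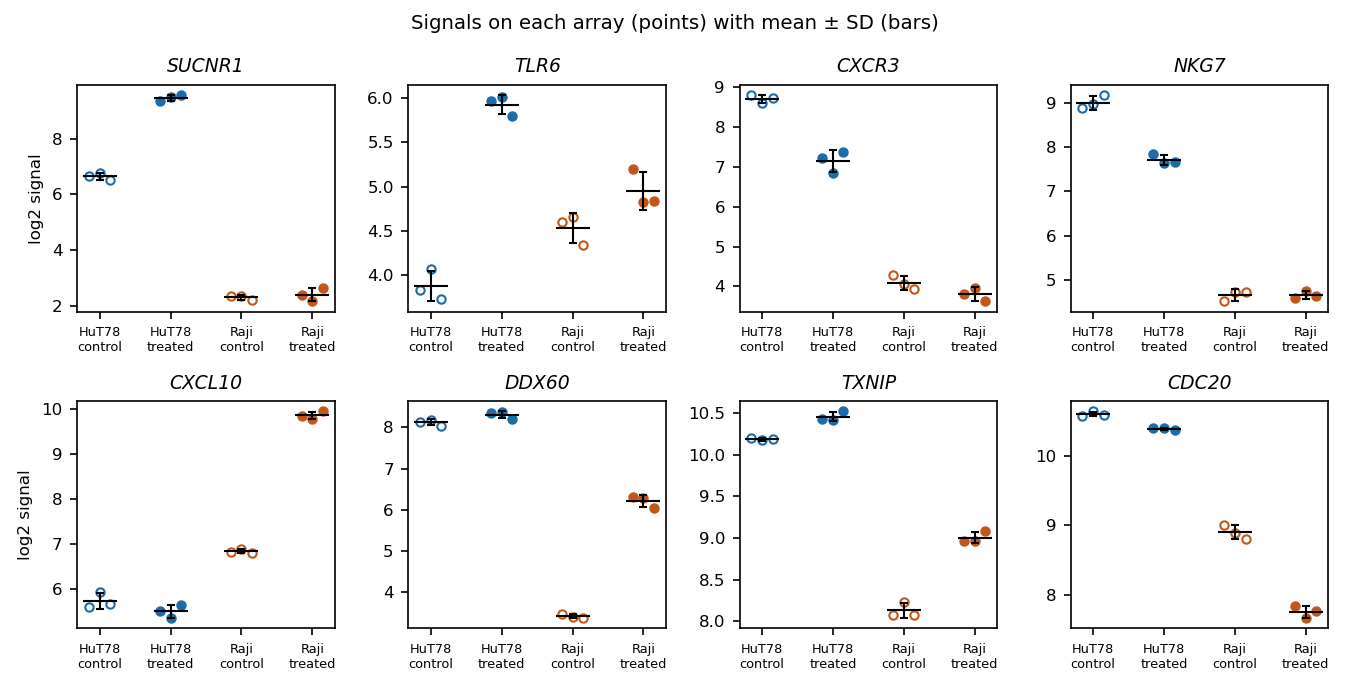
Log2 signal of 8 genes on each of the 12 arrays (points), with the mean and SD of each group of 3 arrays (bars); the lines sit on different scales, so levels compare within a line. SUCNR1 rose from 6.64 to 9.46 in HuT78, and CXCL10 rose from 6.84 to 9.87 in Raji.

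Among the 36 fixed gene lists, 6 passed the camera test in HuT78, and 0 of these passed when the correlation within each list was estimated from the data. The natural killer and cytotoxic genes fell, with 4 of 12 measured members lower, 0 higher and 8 not passing (median -0.18, adjusted p = 5.90e-05; adjusted p = 0.0857 with an estimated correlation). Adjusted over the list alone, 5 members were lower; NKG7 and GZMK led, followed by GNLY, a pore-forming granule protein, at -0.68 ± 0.16. Nucleolar ribosome-biogenesis genes linked to MYC fell, with 3 of 24 lower, 0 higher and 21 not passing (median -0.16, adjusted p = 2.44e-06; adjusted p = 0.144 with an estimated correlation). Adjusted over the list alone, 9 were lower, and examples were BYSL, a factor for small ribosomal subunits (-0.45 ± 0.11), and PUS7, a pseudouridine synthase (-0.35 ± 0.07). DNA replication genes had 2 of 23 members lower, 0 higher and 21 not passing, and 4 lower adjusted over the list alone (median -0.10, adjusted p = 0.00730; adjusted p = 0.130 with an estimated correlation). The members were MCM5, a subunit of the replicative helicase (-0.38 ± 0.08), and CDC45, its partner (-0.34 ± 0.08). Targets of ATF4, the transcription factor of the integrated stress response, rose, with 5 of 17 higher, 0 lower and 12 not passing, and 8 higher adjusted over the list alone (median 0.26, adjusted p = 0.000132; adjusted p = 0.144 with an estimated correlation). PHGDH, the first enzyme of serine synthesis, rose by 0.80 ± 0.10 and ASNS, asparagine synthetase, by 0.70 ± 0.09. Calls of these genes that ended in at least 1 of the 12 fits without 1 array were GNLY (highest adjusted p = 0.116, without treated HuT78 array 3), BYSL (0.125, treated array 1), PUS7 (0.0600, treated array 2), MCM5 (0.0696, treated array 1) and CDC45 (0.0827, treated array 2).

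The other 2 lists called in HuT78 stood close to the threshold. The list of Sezary and cutaneous T-cell lymphoma genes, which mixes genes gained and genes lost in the disease, shifted upward, with 3 of 14 higher, 0 lower and 11 not passing, and 4 higher adjusted over the list alone (median 0.11, adjusted p = 0.0393; adjusted p = 0.144 with an estimated correlation). The 3 were DNM3, a dynamin (1.20 ± 0.11), STAT4, a transcription factor of interleukin-12 signalling (1.03 ± 0.14), and DPP4, the surface peptidase CD26 (0.78 ± 0.12), and STAT4 and DPP4 are genes that Sezary cells lose. This call ended on the 6 HuT78 arrays alone (adjusted p = 0.0570) and without untreated HuT78 array 1 (0.0583), treated HuT78 array 3 (0.0581) or untreated Raji array 3 (0.0579). Cholesterol efflux genes had 1 of 5 members lower, 0 higher and 4 not passing, and 2 lower adjusted over the list alone (median -0.18, adjusted p = 0.0393; adjusted p = 0.144 with an estimated correlation). The member was SREBF1, a transcription factor of lipid synthesis (-0.80 ± 0.14). This call ended after median centring (adjusted p = 0.0534) and without untreated HuT78 array 2 (0.0816), treated HuT78 array 2 (0.101), untreated Raji array 3 (0.0579) or treated Raji array 3 (0.0504).

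Other lists did not pass as a whole in HuT78 but held single genes that did. Of 27 B-cell genes, 6 rose, 1 fell and 20 did not pass (7 higher and 2 lower adjusted over the list alone; median -0.00, mean 0.15, adjusted p = 0.102). These included CD38, an ectoenzyme of activated lymphocytes (1.26 ± 0.10), RASGRP3, an activator of Ras (1.02 ± 0.12), CD24, a surface glycoprotein (0.97 ± 0.10), and STAP1, an adaptor protein (0.67 ± 0.08). Of 27 interferon-stimulated genes, 2 rose, 0 fell and 25 did not pass (2 higher and 1 lower adjusted over the list alone; median 0.08, adjusted p = 0.394). They were RSAD2, which makes an antiviral nucleotide (0.93 ± 0.13), and IFI44 (0.57 ± 0.12). Of 8 growth-arrest genes, 2 rose and 6 did not pass (4 higher and 1 lower adjusted over the list alone; median 0.19, adjusted p = 0.102), namely KLF6, a transcription factor (0.71 ± 0.11), and CCNG2, an atypical cyclin (0.46 ± 0.10). PMAIP1, which encodes the pro-apoptotic protein NOXA, rose by 0.53 ± 0.08 and BCL2A1, an anti-apoptotic relative of BCL2, by 0.75 ± 0.10. HMOX1, haem oxygenase, rose by 0.55 ± 0.11. None of the 26 mitosis genes passed in limma over all genes or adjusted over the list alone (median -0.08, adjusted p = 0.0836). HDAC9 was the single fixed drug-target gene that passed, at 0.51 ± 0.10. Values for DNMT1 (-0.07 ± 0.07), DNMT3A (0.01 ± 0.10), DNMT3B (0.13 ± 0.19), UHRF1 (-0.27 ± 0.08), HDAC1 (-0.12 ± 0.08), HDAC2 (0.08 ± 0.08), HDAC3 (-0.13 ± 0.11), HDAC6 (-0.02 ± 0.12) and MYC (-0.06 ± 0.09) did not pass. Without 1 array, calls ended for IFI44 (highest adjusted p = 0.0769, without untreated HuT78 array 1), CCNG2 (0.0831, untreated array 3), HMOX1 (0.0524, untreated array 1) and HDAC9 (0.0608, treated array 1).

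In Raji the same question was put to a B-cell lymphoma line. CXCL10, an interferon-induced chemokine, rose by 3.03 ± 0.10, which is 8.18-fold (adjusted p = 1.13e-08), and DDX60, an antiviral helicase, rose by 2.80 ± 0.09 (adjusted p = 1.13e-08) from a dim log2 signal of 3.41, under the array medians. CD69, an early activation marker of lymphocytes, rose by 2.45 ± 0.18, SAMD9L, an interferon-induced growth inhibitor, by 2.41 ± 0.09, and IFIT1, which binds viral RNA, by 2.32 ± 0.18. The next largest rises were IFI44 (2.24 ± 0.12), CLIC2, a chloride channel protein (2.06 ± 0.23), and DOCK10, a guanine nucleotide exchange factor (2.04 ± 0.09). NEIL1, a glycosylase of base excision repair, changed by -1.78 ± 0.16 (adjusted p = 1.99e-05). TRIP13, an ATPase of the spindle checkpoint, changed by -1.18 ± 0.09, CDC20, an activator of the anaphase-promoting complex, by -1.15 ± 0.08, and MEPCE, an RNA-capping enzyme, by -1.11 ± 0.10. Further falls were measured for LUC7L, a splicing factor (-1.04 ± 0.11), PRDM10 (-1.03 ± 0.12), NDC1, a nuclear pore protein (-0.98 ± 0.07), and HMGN1, a nucleosome-binding protein (-0.97 ± 0.14). In all, 2590 of 14884 genes passed, 1198 higher and 1392 lower, and 156 changed at least 2-fold (148 higher, 8 lower). The spread within groups was larger in Raji than in HuT78 (median residual SD 0.156 and 0.116), and on the 6 Raji arrays alone 1359 genes passed. In simulated data the spread shared by the lines gave 37 false calls in Raji and 7 in HuT78. The Raji count may therefore hold a larger share of false calls than the threshold allows. After quantile normalization 1519 genes were higher and 1003 lower, so the share of higher genes was 60.2% in place of 46.3%.

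The rising lists in Raji centred on interferon and NF-kB targets. Of 27 interferon-stimulated genes, 20 rose, 0 fell and 7 did not pass, with 22 higher adjusted over the list alone (median 1.17, adjusted p = 5.71e-21; adjusted p = 0.000273 with an estimated correlation). Beside DDX60, IFIT1 and IFI44, IFIT2 rose by 1.82 ± 0.09. Of 17 NF-kB targets, 12 rose, 0 fell and 5 did not pass, with 13 higher adjusted over the list alone (median 0.84, adjusted p = 1.10e-16; adjusted p = 0.000273 with an estimated correlation). Beside CXCL10, these included BCL2A1 (2.01 ± 0.10), EBI3, a cytokine subunit (1.51 ± 0.14), and CCL5, a chemokine (1.44 ± 0.08). Of 8 anti-apoptotic genes, 5 rose, 1 fell and 2 did not pass, the same numbers adjusted over the list alone (median 0.44, adjusted p = 0.000644; adjusted p = 0.0235 with an estimated correlation). BCL2, the founding member of its family, rose by 1.18 ± 0.09 and CFLAR, an inhibitor of caspase-8 activation, by 0.95 ± 0.07, while BIRC5, which also acts in mitosis, changed by -0.63 ± 0.10. Of 8 growth-arrest genes, 4 rose, 0 fell and 4 did not pass, also adjusted over the list alone (median 0.24, adjusted p = 0.00135; adjusted p = 0.0245 with an estimated correlation). KLF6 rose by 1.30 ± 0.11, TXNIP, an inhibitor of thioredoxin, by 0.87 ± 0.08, and RB1, the retinoblastoma protein, by 0.58 ± 0.12. The call of CCNG2, the other member (0.32 ± 0.10), ended in 9 of the 12 fits without 1 array (highest adjusted p = 0.152, without untreated Raji array 1), after median centring (0.0669) and on the 6 Raji arrays alone (0.125). Of 19 lysosome and autophagy genes, 5 rose, 0 fell and 14 did not pass, also adjusted over the list alone (median 0.18, adjusted p = 0.00135; adjusted p = 0.0235 with an estimated correlation). Among them were CTSB and CTSD, lysosomal proteases (0.89 ± 0.13 and 0.48 ± 0.09), and PSAP, the precursor of saposins (0.57 ± 0.08).

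The falling lists in Raji held genes of the cell cycle, ribosome biogenesis and glycolysis. Of 26 mitosis genes, 22 fell, 1 rose and 3 did not pass, with 24 lower and 1 higher adjusted over the list alone (median -0.49, adjusted p = 1.10e-16; adjusted p = 0.0245 with an estimated correlation). Beside CDC20 these included CCNB1, the mitotic cyclin B1 (-0.95 ± 0.08), PLK1, a mitotic kinase (-0.94 ± 0.09), and KIF20A, a kinesin of cytokinesis (-0.82 ± 0.11). The member that rose, BUB1, a checkpoint kinase named here after its value was seen, did so by 0.27 ± 0.08, and this call ended in 10 of the 12 fits without 1 array (highest adjusted p = 0.118, without untreated Raji array 3), after median centring (0.0730) and on the 6 Raji arrays alone (0.169). Of 23 DNA replication genes, 17 fell, 1 rose and 5 did not pass, also adjusted over the list alone (median -0.41, adjusted p = 2.63e-10; adjusted p = 0.00126 with an estimated correlation). CDC6, which loads the replicative helicase, changed by -0.94 ± 0.08 and MCM7, a helicase subunit, by -0.70 ± 0.10, while CCNE1, cyclin E1, rose by 0.76 ± 0.09. Of 24 nucleolar ribosome-biogenesis genes, 18 fell, 0 rose and 6 did not pass, with 22 lower adjusted over the list alone (median -0.46, adjusted p = 1.00e-13; adjusted p = 0.0157 with an estimated correlation). LYAR, a nucleolar regulator (-0.77 ± 0.09), NIP7, a ribosome assembly factor (-0.76 ± 0.08), and NOP2, an RNA methyltransferase (-0.70 ± 0.11), were among them. Of 9 glycolysis genes, 6 fell, 0 rose and 3 did not pass, with 7 lower adjusted over the list alone (median -0.40, adjusted p = 4.98e-05; adjusted p = 0.0151 with an estimated correlation). They included the enzymes PGK1 (-0.67 ± 0.08), GPI (-0.54 ± 0.07), HK2 (-0.51 ± 0.09) and LDHA (-0.45 ± 0.08).

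**Figure D2:**
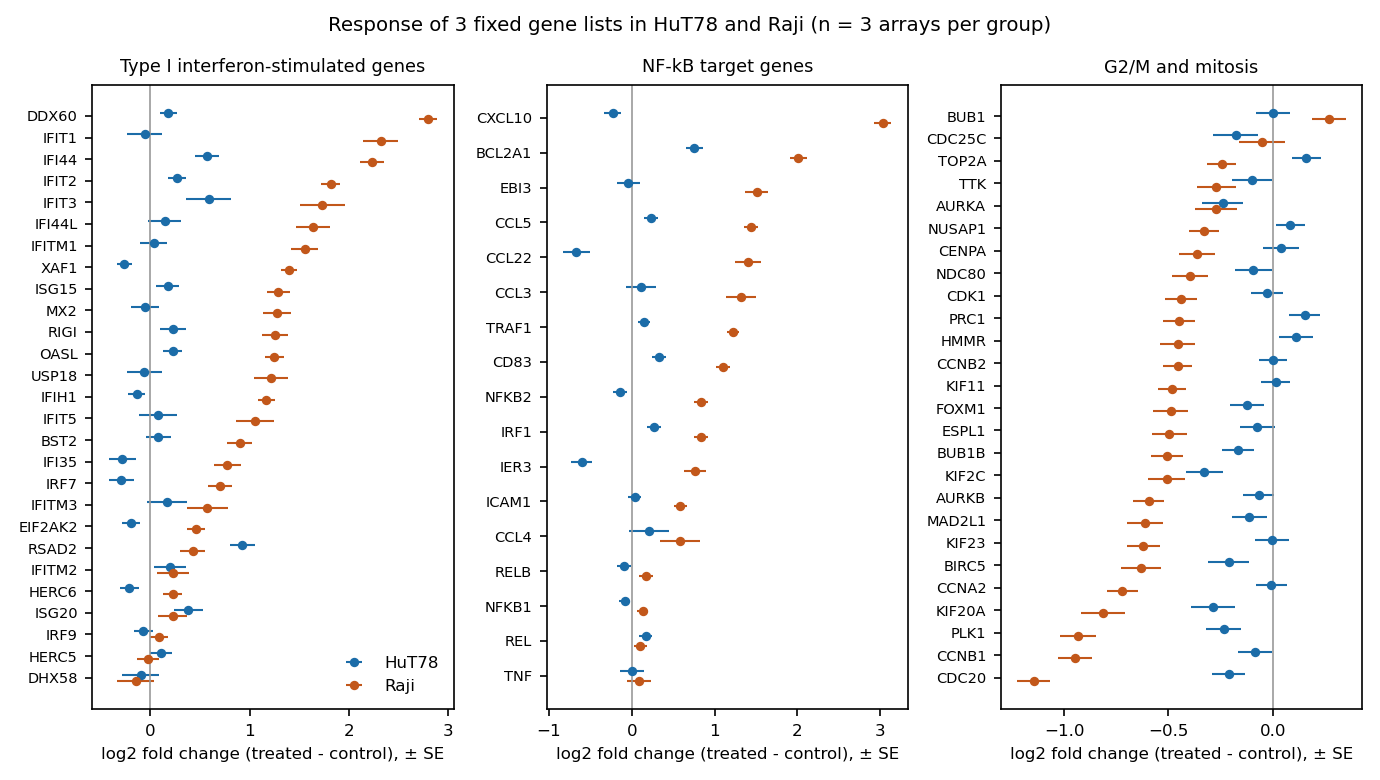
Log2 fold change ± SE of every measured member of the interferon, NF-kB and mitosis lists in HuT78 (blue) and Raji (orange), with 3 arrays per group. In Raji 20 of 27 interferon-stimulated genes and 12 of 17 NF-kB targets rose and 22 of 26 mitosis genes fell.

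For 5 further lists the call in Raji was lost when the correlation was estimated. Of 13 genes of homologous recombination, 4 fell, 0 rose and 9 did not pass, with 6 lower and 1 higher adjusted over the list alone (median -0.28, adjusted p = 0.00206; adjusted p = 0.146 with an estimated correlation). XRCC2, a protein of double-strand break repair, changed by -0.77 ± 0.08 and RAD54L, a motor protein of strand exchange, by -0.59 ± 0.08. Of 17 cholesterol synthesis genes, 5 fell, 1 rose and 11 did not pass, with 8 lower and 1 higher adjusted over the list alone (median -0.27, adjusted p = 0.0119; adjusted p = 0.450 with an estimated correlation). ACAT2, a thiolase, changed by -0.85 ± 0.17, and the list's call ended without untreated Raji array 3 (adjusted p = 0.272) or treated Raji array 2 (0.0533). Of 27 B-cell genes, 9 rose, 4 fell and 14 did not pass, with 12 higher and 4 lower adjusted over the list alone (median 0.15, adjusted p = 0.0236; adjusted p = 0.199 with an estimated correlation). FCRL2 (1.72 ± 0.10) and FCRL1 (0.97 ± 0.13), Fc receptor-like proteins, and BANK1, a B-cell scaffold protein (0.90 ± 0.10), rose, while BCL6, a repressor of germinal-centre B cells, changed by -0.70 ± 0.12. The B-cell list's call ended without untreated Raji array 2 (median 0.057, adjusted p = 0.0528) or treated Raji array 3 (median 0.091, adjusted p = 0.0531). Of the 14 genes gained or lost in Sezary and cutaneous T-cell lymphoma, 5 rose, 0 fell and 9 did not pass, with 5 higher and 1 lower adjusted over the list alone (median 0.12, adjusted p = 0.0294; adjusted p = 0.0976 with an estimated correlation). SATB1, a chromatin organiser that Sezary cells lose, rose by 0.91 ± 0.12 and JUNB, an AP-1 subunit, by 0.64 ± 0.16. The list's call ended after quantile normalization (adjusted p = 0.0613) and without untreated Raji array 3 (0.0670) or treated Raji array 2 (0.111), and that of JUNB ended on the 6 Raji arrays alone (adjusted p = 0.0650). Of 9 heat-shock genes, 2 fell, 0 rose and 7 did not pass, with 4 lower adjusted over the list alone (median -0.18, adjusted p = 0.0294; adjusted p = 0.146 with an estimated correlation). These were the co-chaperones CHORDC1 (-0.66 ± 0.10) and STIP1 (-0.44 ± 0.07). That call ended after quantile normalization (adjusted p = 0.0990), with dim genes left out (0.0641), on the 6 Raji arrays alone (0.0534) and without treated Raji array 1 (0.0774) or 2 (0.0569).

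Of 14 p53 targets, 4 rose in Raji, 0 fell and 10 did not pass, also adjusted over the list alone, and the list did not pass (median 0.13, adjusted p = 0.0571). TP53INP1, which acts in stress-induced cell death, rose by 1.86 ± 0.11 and SESN1, a stress-induced inhibitor of TOR signalling, by 0.78 ± 0.11. PMAIP1 rose by 0.91 ± 0.08. Among 26 T-cell genes 7 rose, 0 fell and 19 did not pass, also adjusted over the list alone (median 0.04, adjusted p = 0.0842); CCR7, a lymph node homing receptor, rose by 1.52 ± 0.09 and IL7R, the interleukin-7 receptor, by 0.90 ± 0.10. HDAC9 rose by 0.57 ± 0.10. DNMT1, the maintenance DNA methyltransferase, changed by -0.33 ± 0.07, UHRF1, its recruiter, by -0.31 ± 0.08 and HDAC1 by -0.28 ± 0.08. These 3 calls ended on the 6 Raji arrays alone (adjusted p = 0.0580 for DNMT1, 0.104 for UHRF1 and 0.129 for HDAC1), and those of UHRF1 and HDAC1 also after quantile normalization (-0.21, adjusted p = 0.110, and -0.19, adjusted p = 0.124). With 1 array left out, the highest adjusted p was 0.0716 for UHRF1 (untreated Raji array 3) and 0.0757 for HDAC1 (treated Raji array 1). DNMT3A (0.02 ± 0.10), DNMT3B (0.12 ± 0.19), HDAC2 (-0.09 ± 0.08), HDAC3 (-0.02 ± 0.11), HDAC6 (-0.01 ± 0.12) and MYC (-0.26 ± 0.09) did not pass. Only 14 of the 40 genes on the cancer-testis list were measured. Of these 14, 0 passed in limma in either line, over all genes or adjusted over the list alone (median 0.02 in HuT78 and 0.05 in Raji).

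**Figure D3:**
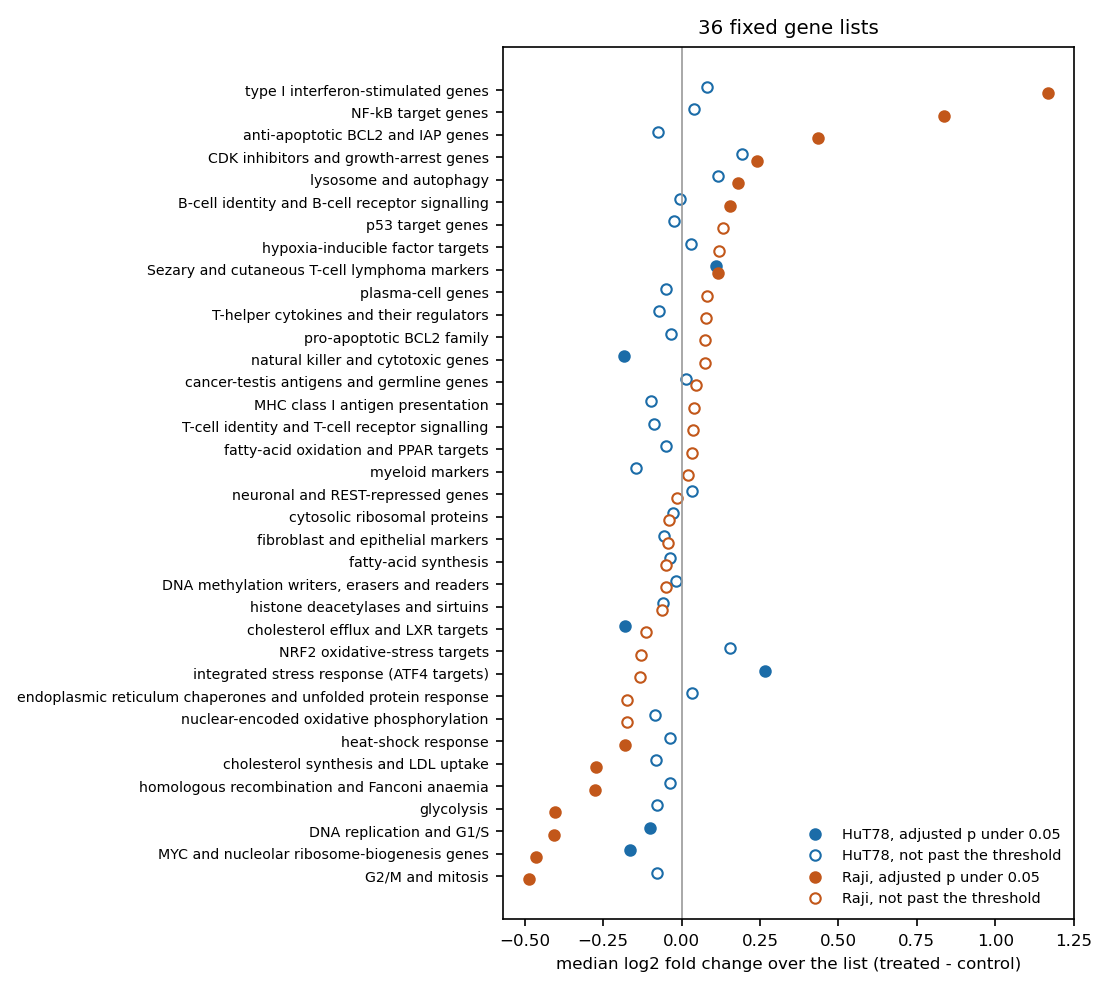
Median log2 fold change of 36 fixed gene lists in HuT78 (blue) and Raji (orange); filled points passed an adjusted p of 0.05 in the camera test with its preset correlation. The interferon list had a median of 1.17 in Raji and 0.08 in HuT78, and the mitosis list -0.49 and -0.08.

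Whether the responses of the lines differed was tested directly as the HuT78 effect minus the Raji effect. The largest positive differences were SUCNR1 (2.73 ± 0.17, adjusted p = 9.05e-06), NEIL1 (1.79 ± 0.22), TLR6 (1.63 ± 0.19), HMGN5 (1.58 ± 0.12) and DNM3 (1.499 ± 0.15). The largest negative ones were CXCL10 (-3.26 ± 0.14, adjusted p = 5.63e-07), DDX60 (-2.62 ± 0.13), IFIT1 (-2.38 ± 0.25), CLIC2 (-2.24 ± 0.33) and FCRL5, an Fc receptor-like protein (-2.17 ± 0.40). In untreated HuT78 cells CLIC2 (log2 signal 3.89), FCRL5 (4.13) and IFIT1 (4.93) were dim, under the array medians, which limits what the size of these differences shows. In all, 900 of 14884 genes differed, 501 with a positive and 399 with a negative difference. Without 1 array the count was 550 and 525 (untreated HuT78 array 1 or 3) and 581, 543 and 565 (treated HuT78 array 1, 2 or 3). After quantile normalization 329 differences were positive and 444 negative, so the share of positive ones was 42.6% in place of 55.7%.

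Of the 36 lists, 13 differed between the lines, and 6 of these also with an estimated correlation. Interferon-stimulated genes responded less in HuT78, with 17 of 27 differences negative, 0 positive and 10 not passing, and 20 negative and 1 positive adjusted over the list alone (median -1.03, adjusted p = 1.36e-20; adjusted p = 0.000291 with an estimated correlation). XAF1, a pro-apoptotic interferon target, differed by -1.66 ± 0.11. For NF-kB targets 12 of 17 differences were negative, 0 positive and 5 not passing, also adjusted over the list alone (median -0.98, adjusted p = 3.38e-18; adjusted p = 0.000291 with an estimated correlation), among them CCL22, a chemokine (-2.07 ± 0.23). Of 8 anti-apoptotic genes, 4 differed negatively, 0 positively and 4 did not pass, with 5 negative and 1 positive adjusted over the list alone (median -0.54, adjusted p = 3.95e-05; adjusted p = 0.0145 with an estimated correlation), and BCL2 differed by -1.35 ± 0.13. DNA replication genes had 6 of 23 positive, 1 negative and 16 not passing, with 13 and 1 adjusted over the list alone (median 0.31, adjusted p = 1.75e-05; adjusted p = 0.0114 with an estimated correlation), and CDC6 differed by 0.69 ± 0.11. Cytotoxic genes had 2 of 12 negative, 0 positive and 10 not passing, with 4 negative adjusted over the list alone (median -0.28, adjusted p = 0.000174; adjusted p = 0.0330 with an estimated correlation). Glycolysis had 1 of 9 positive, 0 negative and 8 not passing, with 2 positive adjusted over the list alone (median 0.25, adjusted p = 0.00141; adjusted p = 0.0355 with an estimated correlation), the gene being PGK1 (0.60 ± 0.11). The mitosis list, with 14 of 26 positive, 0 negative and 12 not passing (21 and 1 adjusted over the list alone; median 0.42, adjusted p = 3.48e-13), had an adjusted p = 0.0574 with an estimated correlation.

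The responses also shared genes. Across 14884 genes the effects in the lines correlated with a Pearson coefficient of 0.280 and a Spearman coefficient of 0.263, where genes are not independent replicates. Of the 365 genes that passed in both lines, 233 rose in both (52.3 for independent lists) and 104 fell in both (22.4), while 14 rose in HuT78 and fell in Raji (60.8) and 14 did the opposite (19.2). The following examples were chosen after their values were seen. MIR21, the gene of an oncogenic microRNA, rose by 1.40 ± 0.12 in HuT78 and 1.82 ± 0.12 in Raji, and JUN, an AP-1 subunit, by 1.39 ± 0.16 and 1.69 ± 0.16. SYT11, a synaptotagmin of the neuronal list, rose by 1.19 ± 0.13 and 1.42 ± 0.13, SLAMF7 by 1.59 ± 0.09 and 1.18 ± 0.09, and MAML2, a coactivator of Notch, by 1.17 ± 0.10 and 1.05 ± 0.10. CD69 rose by 1.02 ± 0.18 and 2.45 ± 0.18, a difference that passed (adjusted p = 0.00620). Opposite changes were found for CCL22 (-0.67 ± 0.16 in HuT78, 1.40 ± 0.16 in Raji), CTSH, a lysosomal protease (-0.64 ± 0.10 and 0.63 ± 0.10), NCR3LG1, a ligand of natural killer cells (0.59 ± 0.13 and -0.68 ± 0.13), and BCL6 (0.55 ± 0.12 and -0.70 ± 0.12). The HuT78 calls ended in fits without 1 array for CCL22 (highest adjusted p = 0.128, untreated HuT78 array 1), NCR3LG1 (0.0912, untreated array 3) and BCL6 (0.0918, untreated array 1), and for CCL22 also on the 6 HuT78 arrays alone (0.0640). The 337 genes with the same direction became 176, 200 and 150 without untreated HuT78 array 1, 2 or 3, and 170, 167 and 186 without treated array 1, 2 or 3.

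**Figure D4:**
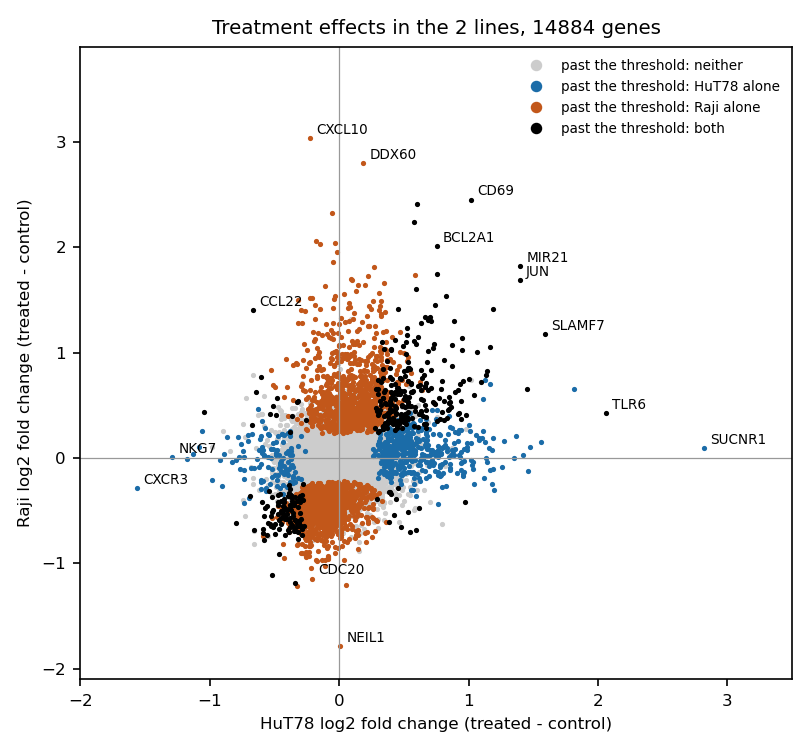
Log2 fold change in Raji against that in HuT78 for 14884 genes, coloured by the line or lines in which the adjusted p was under 0.05; Pearson r across genes was 0.280. CXCL10 and DDX60 lie high on the Raji axis, SUCNR1 far out on the HuT78 axis, and MIR21 and JUN far out on both.

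The untreated lines were compared only to check the cell line labels, since their arrays sit on different scales. AHR, a ligand-activated transcription factor (8.67 ± 0.09), CCR4, a chemokine receptor of T cells (8.41 ± 0.08), GPR15, a homing receptor of T cells (8.40 ± 0.13), CD96, a receptor of T and natural killer cells (7.91 ± 0.20), and LCP2, an adaptor of T-cell receptor signalling (7.82 ± 0.12), were higher in HuT78. CD180 (-6.57 ± 0.16) and CD22 (-6.44 ± 0.12), B-cell surface proteins, RGS13 (-5.57 ± 0.14), CDK14 (-5.52 ± 0.10) and CR2, the complement receptor CD21 (-5.19 ± 0.10), were lower. Of 26 T-cell genes, 25 were higher, 1 lower and 0 not passing, also adjusted over the list alone (median 4.57, adjusted p = 0.00757; adjusted p = 0.0734 with an estimated correlation). Of 27 B-cell genes, 22 were lower, 4 higher and 1 not passing, also adjusted over the list alone (median -2.06, adjusted p = 5.17e-115). The fit called 14583 of 14884 genes, 14281 higher and 302 lower, around a median shift of 1.56. After quantile normalization, which sets the median shift to 0.02, it called 8285 (4534 higher, 3751 lower), and after median centring, with a shift of -0.26, it called 9957 (3009 higher, 6948 lower).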

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

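Of the tests in this part, the splits of the arrays of 1 line, the test of a shared spread and the tests of 1 Raji array and of both lines for the unnamed clusters were chosen after the result was seen. All values in the next paragraphs are HuT78 effects minus Raji effects on the log2 scale, from a direct limma test of the difference, and each stands here because the lines differed in it.

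Negative differences were called for 17 of 27 interferon-stimulated genes and 12 of 17 NF-kB targets, and the other members did not pass. Adjusted over the list alone, 1 interferon-stimulated gene had a positive difference. The list medians were -1.03 for interferon-stimulated genes and -0.98 for NF-kB targets. Single interferon targets were DDX60 (-2.62), IFIT1 (-2.38), SAMD9L (-1.81), IFI44 (-1.66), XAF1 (-1.66) and IFIT2 (-1.55). Chemokines and cytokines were CXCL10 (-3.26), CCL22 (-2.07), CCL3L1 (-1.74), CXCL9 (-1.60), EBI3 (-1.55), CCL5 (-1.21) and CCL3 (-1.21). CCL22 fell in HuT78 and rose in Raji, and so did IER3, an early response gene, which stood at -1.37. The clusters of IER3 disagreed, and over their mean the HuT78 fall did not pass (-0.28, adjusted p = 0.105). The call of CCL3 ended without treated HuT78 array 2 (adjusted p = 0.0502). Anti-apoptotic genes had a list median of -0.54, with BCL2 (-1.35), BCL2A1 (-1.25) and CFLAR (-0.93), and TP53INP1 stood at -1.91. Surface and signalling genes of lymphocytes were FCRL5 (-2.17), CCR7 (-1.73), FCRL2 (-1.50), CD69 (-1.43), BANK1 (-1.23), FCRL1 (-1.14), IL7R (-1.14) and RGS1 (-0.71), and the list of T-cell genes had a median of -0.072, a call lost with an estimated correlation (adjusted p = 0.0708). Further genes were CLIC2 (-2.24), DOCK10 (-2.07), CTSH (-1.27, opposite changes), CCNE1 (-0.77), CTSB (-0.75), YPEL3 (-0.74), YPEL5 (-0.71), TXNIP (-0.60) and KLF6 (-0.59), and the growth-arrest list had a median of -0.20. In untreated HuT78 cells CXCL9 (log2 signal 3.43), CLIC2 (3.89), FCRL2 (4.08), FCRL5 (4.13), BANK1 (4.23), TP53INP1 (4.48) and IFIT1 (4.93) stood under the array medians (5.39 to 5.41), and so did DDX60 (3.41) in untreated Raji cells, so the size of their differences rests on signals not shown to be above background. Among the genes of this paragraph, 4 calls ended in 9 or 10 of the 12 fits without 1 array: RGS1 (highest adjusted p = 0.0896, without untreated HuT78 array 3), YPEL3 (0.0925, the same array), CTSB (0.0857, untreated HuT78 array 2) and KLF6 (0.112, untreated HuT78 array 1). Median centring also ended the calls of RGS1 (adjusted p = 0.0516) and KLF6 (0.0688). The growth-arrest list's call ended without treated HuT78 array 2 (adjusted p = 0.0538) and with an estimated correlation (adjusted p = 0.0904).

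Falls of HuT78 lay behind the genes of this paragraph, among them the 2 of 12 cytotoxic genes whose difference passed. The cytotoxic list had a median of -0.28, with GZMK at -1.32 and NKG7 at -1.30. LGMN stood at -1.48, with a rise in Raji beside its fall in HuT78, CXCR3 at -1.27, TLR5 at -1.18, SUSD4 at -1.17 and NSMF at -1.17. In untreated Raji cells GZMK (log2 signal 2.31), TLR5 (2.78) and SUSD4 (3.32) stood under the array medians (3.67 to 3.73), where little room was left for a fall, so these differences do not show that Raji cells resisted one.

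Genes with a positive difference rose more in HuT78 or fell more in Raji. Rises of HuT78 lay behind SUCNR1 (2.73), TLR6 (1.63), HMGN5 (1.58), DNM3 (1.499), HIPK2 (1.40), ATRNL1 (1.39), CD38 (1.34), LAIR2 (1.16), RASGRP3 (1.09), STAT4 (1.07), RGS18 (0.98), CD24 (0.89), DPP4 (0.86) and TPMT (0.80). In untreated Raji cells LAIR2 (log2 signal 2.10), RGS18 (2.15), SUCNR1 (2.29), CD24 (2.38), ATRNL1 (2.39), STAT4 (2.62), HMGN5 (2.82), DNM3 (2.95) and DPP4 (3.33) also stood under the array medians, so the size of their differences rests on signals not shown to be above background. In untreated HuT78 cells RGS18 (3.29), TLR6 (3.87), CD24 (4.62), DNM3 (4.99) and ATRNL1 (5.31) stood under the medians of those arrays. The call of LAIR2 ended in 9 of the 12 fits without 1 array (highest adjusted p = 0.114, without treated HuT78 array 2), after quantile normalization (0.98, adjusted p = 0.192) and after median centring (adjusted p = 0.0572). Stress genes were PHGDH (1.07), HMOX1 (0.85) and ASNS (0.74), with list medians of 0.35 for ATF4 targets and 0.21 for NRF2 targets, calls lost with an estimated correlation (adjusted p = 0.118 and 0.0904). GARS1, a tRNA synthetase, stood at 0.61. Opposite changes lay behind NCR3LG1 (1.27) and BCL6 (1.252).

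Falls of Raji lay behind the proliferation genes. List medians were 0.42 for mitosis, 0.31 for DNA replication, 0.31 for ribosome biogenesis, 0.25 for glycolysis and 0.23 for homologous recombination. With an estimated correlation the calls of mitosis (adjusted p = 0.0574), ribosome biogenesis (0.0909) and recombination (0.229) were lost. Mitosis and replication genes were CDC20 (0.93), CCNB1 (0.86), TRIP13 (0.84), CCNA2, cyclin A2 (0.71), PLK1 (0.70) and CDC6 (0.69). Repair, metabolic and ribosome genes were NEIL1 (1.79), PGK1 (0.60), RAD54L (0.53), XRCC2 (0.52), LYAR (0.52) and NIP7 (0.50). The rest were HMGN1 (1.01), PRDM10 (0.92), LUC7L (0.83), NDC1 (0.81), MEPCE (0.59) and CHORDC1 (0.53). Calls that ended without 1 array were those of LYAR (highest adjusted p = 0.0943), MEPCE (0.0810), CHORDC1 (0.113) and XRCC2 (0.0529), each highest without untreated HuT78 array 1, and NIP7 (0.0574, without treated HuT78 array 2). They ended in 9, 8, 10, 1 and 2 of the 12 fits. Quantile normalization also ended the calls of LYAR (adjusted p = 0.0856), CHORDC1 (0.0766) and MEPCE (0.0523), and median centring those of CHORDC1 (0.0749) and MEPCE (0.0519). The call of the recombination list ended after quantile normalization (median 0.16, adjusted p = 0.0780). It also ended without treated HuT78 array 2 (median 0.15, adjusted p = 0.0791) or treated Raji array 1 (median 0.093, adjusted p = 0.0582).

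In all 900 genes differed, and 1 of 100 joint splits of the arrays of both lines, the real one, gave as many (highest other 780). Untreated array 1 of each line stayed on the untreated side in all of these splits. None of them therefore swapped the untreated and treated arrays of 1 line alone, which also changes the difference. Some splits kept the real grouping of 1 line. For these reasons the share does not decide whether a random grouping gives as many genes. For the 13 lists that differed, 7 of the 100 splits gave as many (highest other 17), so a random grouping was not excluded for their number.

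The larger rise of interferon genes in Raji may be a biological difference between the lines, a hypothesis found and tested on the same data. The errors in this paragraph come from resampling the list members, which are not independent replicates, and hold no variation between arrays. A compressed low end of the HuT78 scale was argued against by the median difference after quantile normalization, -1.05 ± 0.135. Members too dim on the HuT78 arrays were argued against by the 24 of 27 members above the array median in untreated HuT78 cells, whose median difference was -1.01 ± 0.168. A single Raji array was argued against by the lowest list median in Raji with 1 array left out, 1.09 ± 0.208. Whether members already high in untreated HuT78 cells had less room to rise was not tested. In untreated cells 25 of the 27 members were higher in HuT78 than in Raji, on scales that differ. Their median was 2.06, beside a median shift of 1.56 over all genes. The lines differ at least in cell type, disease and donor, and which of these matters was not tested. Each line also had its own array scale, so line and scale cannot be fully separated here.

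More genes passed in Raji than in HuT78, by a ratio of 2.91, and the estimate of spread shared by the lines may account for part of this. With each line fitted on its own arrays the ratio was 1.26, under the bound of 1.5 set for that explanation. These fits also had fewer degrees of freedom, and the effects of the spread and of the degrees of freedom were not separated. In simulated data the shared spread gave 37 false calls in Raji, and the 6 Raji arrays alone gave 12. A compressed low end of the HuT78 scale was argued against as the whole cause by 3032 bright genes. Over these the noise-corrected SD of effects was 0.182 in HuT78 and 0.311 in Raji, a ratio of 1.71 ± 0.0454 (error from resampling genes). A compressed bright end of the HuT78 scale would also lower the HuT78 SD, so these genes cannot speak against it. Over all genes the SDs lay closer together, at 0.188 and 0.256.

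Clusters without a gene name were outside the comparisons of the report, and among 37519 of them 408 changed in HuT78 and 2692 in Raji (1038 higher, 1654 lower). The 3575 unnamed clusters with the lowest IDs had a median change of -0.28 in Raji, with 71.1% of them lower and 413 called lower against 14 higher. A fall of signals of that level was argued against by named genes matched on level, whose median change was 0.00994 ± 0.00445. A single array was argued against by the highest median with 1 Raji array left out, -0.240 ± 0.0105. The clusters also fell in HuT78, with 59.3% of them lower and 9 called lower against 6 higher. Their HuT78 median, -0.0780 ± 0.00670, argued against an equal fall in both lines but not against a smaller one in HuT78. These errors come from resampling clusters, or from random draws for the matched genes, and hold no variation between arrays. What these clusters measure is not given in the sources used here, and no biological explanation was tested.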

How the results depend on the processing

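In this part the spread estimated per line for the difference and the own arrays of each line for the overlap were chosen after the data were seen. The alternatives were run on 360 called gene results, a wider set than the genes named in the text; 6714 repeats of these kept direction and side of the threshold and 1202 did not pass. For lists these were 763 and 63, and in 0 cases did a called value reverse.

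Without 1 array or 1 replicate number the counts were 139 to 964 (HuT78, from 889), 1137 to 2423 (Raji, from 2590), 122 to 845 (difference, from 900), 14422 to 14595 (untreated) and 33 to 343 (shared, from 337), and the correlation was 0.234 to 0.275. The lowest counts came without replicate 1, which left fewer arrays. The lists numbered 4 to 8 (HuT78), 11 to 15 (Raji), 11 to 15 (difference) and 6 to 8 (untreated).

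A block for the replicate number gave 513 genes in HuT78, 500 for the difference and 165 shared, and it spends degrees of freedom. After each gene's group mean was subtracted, correlations of untreated with treated arrays of the same line and number were -0.0332 to 0.0746. They gave no clear sign of pairing, but with 3 arrays per group they cannot exclude it. The block also ended the HuT78 calls of the Sezary list (adjusted p = 0.0772) and the cholesterol efflux list (0.0572), and the Raji calls of UHRF1 (0.0732), HDAC1 (0.0693), BUB1 (0.0646) and CCNG2 (0.0698). Among genes of the text it ended in HuT78 those of BYSL (0.0769), PUS7 (0.0502), MCM5 (0.0572), CDC45 (0.0576), HMOX1 (0.0535), IER3 (0.0715) and MRPL27 (0.0804). For the difference it ended those of HIPK2 (0.0579), DPP4 (0.0597), RAD54L (0.0705), XRCC2 (0.0727), LAIR2 (0.0780), CTSB (0.0948), YPEL3 (0.108), LYAR (0.112), NIP7 (0.0769), CHORDC1 (0.0608) and MEPCE (0.0501). On its own 6 arrays Raji had 1359 genes. Trend and robust settings gave 1366 for the difference and 567 shared. Over all clusters, where more features were tested, Raji had 4675, the untreated lines 51154 and the correlation was 0.208; with dim genes left out (10941 kept) it was 0.323. Quantile normalization gave 8285 for the untreated lines. A 2-fold threshold left 58 (unadjusted p) and 57 (adjusted p) in HuT78, 157 and 156 in Raji, and 186 and 164 for the difference. The spread per line gave 957 for the difference, and own arrays gave 252 shared. Apart from the thresholds and the fewer or more arrays and features, the cause was not tested.

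Camera with an estimated correlation called 0 lists in HuT78, 9 in Raji, 6 for the difference and 3 for the untreated lines, and fry 14, 24, 20 and 36. Lists need gene names, so they were not run on all clusters. Signals of dim genes limit what can be seen.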

Other observations

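Of the tests in this part, the splits of the arrays of 1 line were chosen only after the results were seen. The gene families of the next paragraphs were picked because their members were seen among the changed genes, so a test of the families on the same data decides nothing, and only member counts over all genes in limma are given.

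In Raji, 6 of 8 Fc receptor-like genes, which encode B-cell surface receptors, were higher and 0 lower (median 0.98). FCRL5 rose by 2.03 ± 0.28, beside FCRL2 (1.72 ± 0.10). Of 39 chemokine ligands, 8 were higher and 0 lower (median 0.13), among them CXCL9 (1.698 ± 0.14), CCL3L1 (1.63 ± 0.16) and CCL3 (1.32 ± 0.18). Of 5 YPEL genes, a small family of zinc-binding proteins, 3 were higher and 0 lower (median 0.73), with YPEL5 (1.45 ± 0.10) and YPEL3 (1.15 ± 0.13) among them. Of 8 AP-1 subunits, 5 were higher and 0 lower (median 0.61). Of 73 mitochondrial ribosomal proteins, 31 were lower and 0 higher (median -0.27), such as MRPL27 (-0.69 ± 0.09) and MRPS7 (-0.59 ± 0.08). Of 17 aminoacyl-tRNA synthetases, 8 were lower and 0 higher (median -0.25), among them GARS1 (-0.42 ± 0.07).

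In HuT78, 4 of 73 mitochondrial ribosomal proteins were lower and 0 higher (median -0.14), such as MRPS7 (-0.46 ± 0.08) and MRPL27 (-0.40 ± 0.09), whose call ended in 5 of 12 fits without 1 array (highest adjusted p = 0.0963, without untreated HuT78 array 1). Of 20 RGS genes, regulators of G-protein signalling, 3 were higher and 0 lower (median 0.17): RGS18 rose by 1.13 ± 0.11, RGS9 by 0.93 ± 0.10 and RGS1 by 0.82 ± 0.12.

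Of the 36 fixed lists, 17 passed in at least 1 line, 3 in both and 19 in neither. Lists of the drugs' targets were among the 19: DNA methylation genes had medians of -0.02 in HuT78 and -0.05 in Raji (adjusted p = 0.890 and 0.393), and histone deacetylases and sirtuins -0.06 and -0.06 (0.712 and 0.923), with a mean of 0.01 in Raji. Cancer-testis antigens, with 0 of 14 measured members (of 40 fixed) changed in either line in limma, had 0.02 and 0.05 (0.815 and 0.586). Death and stress lists were p53 targets at -0.02 and 0.13 (0.796 and 0.0571), with a mean of 0.04 in HuT78, and pro-apoptotic BCL2 genes at -0.03 and 0.08 (0.902 and 0.141), with a mean of 0.02 in HuT78. NRF2 targets stood at 0.16 and -0.13 (0.210 and 0.202), chaperones of the endoplasmic reticulum at 0.03 and -0.17 (0.394 and 0.327), and targets of hypoxia-inducible factor at 0.03 and 0.12 (0.527 and 0.300).

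Identity and immune lists that passed in neither line were T-cell genes at -0.09 and 0.04 (adjusted p = 0.235 and 0.0842), plasma-cell genes at -0.05 and 0.08 (0.366 and 0.300), with a mean of 0.26 in HuT78, and MHC class I genes at -0.10 and 0.04 (0.684 and 0.816). T-helper cytokines had -0.07 and 0.08 (0.394 and 0.327), myeloid markers -0.15 and 0.02 (0.102 and 0.799), fibroblast and epithelial markers -0.06 and -0.04 (0.394 and 0.603), with a mean of 0.03 in Raji, and neuronal genes 0.03 and -0.02 (0.394 and 0.826), with a mean of 0.04 in Raji. Metabolic lists were oxidative phosphorylation at -0.08 and -0.17 (0.0766 and 0.0540), fatty-acid synthesis at -0.04 and -0.05 (0.684 and 0.310) and fatty-acid oxidation at -0.05 and 0.03 (0.796 and 0.241), with a mean of 0.03 in HuT78. Ribosomal proteins had -0.03 and -0.04 (0.366 and 0.327).

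Each comparison of 3 with 3 arrays allows 10 splits, too few for a share under 0.05. The real split and the highest other gave 889 and 0 genes in HuT78, 2590 and 1 in Raji, and 14583 and 0 for the untreated lines. For lists they gave 6 and 1 in HuT78, 14 and 7 in Raji, and 7 and 6 for the untreated lines. For the correlation of the effects, 0.280, 1 of 100 joint splits gave as much (highest other 0.176). That share speaks only against a random grouping of both lines at once. With the real grouping kept in 1 line, the other has 10 splits, too few to decide whether its own grouping was random. For the 337 genes with the same direction 1 of 100 did (highest other 0), which follows from the few calls that other splits gave within a line and adds no test to those.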
